A study of Mus musculus with 2 samples.

How the data were processed

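Total RNA sequencing libraries of embryonic mouse heart were deposited for 2 pools of hearts at embryonic day 16.5, from male and female embryos of strain B6NCrl. Per the labels, the libraries are biological replicates 1 and 2 of a single group, with 1 technical replicate each. Both carry the same donor identifier in the labels, which give separate biosamples but no litter or dissection day; they were treated as separate pools. Per the labels' protocols, RNA was extracted with a mirVana kit, RNA longer than 200 nt was kept, 10 ng went into each library, ERCC spike-in RNAs were added, and a SMARTer Ultra Low kit manual is listed. Whether reads were assigned by strand, and which aligner and quantification tool were used, are not given in the sources used here; the column names are those that RSEM writes.

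Per the file headers and the notes deposited with them, the authors quantified reads on genome build mm10 with annotation M4, 1 library per table and with no pooling of replicates. The deposited gene and transcript tables hold estimated counts, which need not be whole and are not normalized, and their posterior means. TPM values were computed by the authors over all rows of a table, spike-ins included, with effective length equal to length minus 99 bases. The deposited tables also give FPKM, which was not used here, and credibility intervals of TPM whose level the file headers do not state. A TPM value can lie outside its interval, as for Actc1 in replicate 1 (12648 TPM, interval 12344 to 12418). The rules for 2-fold differences and for gene pairs used both. The deposited transcript tables give each transcript's percent of its gene's TPM. Since the values are length-corrected estimates, short genes and genes with near-identical copies carry more error than their counts show, and spike-ins take a share of the total.

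The gene tables hold 69691 rows, of which 43346 carry Ensembl gene identifiers, 26248 a numeric identifier, 96 name ERCC spike-ins and 1 phiX. Names, gene classes and coordinates were taken from GENCODE M21 on GRCm38, the same assembly as mm10, by identifier without version; 42462 of the gene identifiers matched, and unmatched ones held 0.150% and 0.163% of the counts. Of 101510 matched transcripts, 90.1% had the same length in M21 as in the tables. Numeric, spike-in and phiX rows stayed out of library sizes and comparisons. Numeric rows held 0.00013% and 0.00017% of the counts. Spike-ins held 1.62% of the counts in replicate 1 and 3.41% in replicate 2.

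Replicate 1 had 37160624 estimated counts and replicate 2 had 40360242. A gene of 1500 nt with 0 counts may have had up to 3, which is 0.0802 TPM in replicate 1 and 0.0722 TPM in replicate 2. Reads without molecular identifiers are not independent molecules, so floors and the authors' intervals cover counting and assignment error only. With 1 group there was no comparison of conditions, and with 2 libraries an exact two-sided sign-flip test cannot go below p = 0.5, so no p-value was computed. Statements about differences compare these libraries.

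The following choices were made before the data were examined: the gene lists, gene pairs, isoform genes, thresholds and the rule for named genes. The named genes are the 20 nuclear protein-coding genes with the highest mean TPM, up to 5 members per list with the highest mean TPM, list members under 0.1 TPM in both libraries where the text calls them near the floor, the genes of the fixed pairs and the isoform genes, and the 10 genes with the largest log2 ratio in each direction among those more than 2-fold apart. The single values of some of these genes are not reported here, though the list medians and the counts of isoform genes include them. The 37 lists hold 517 symbols, of which 515 were measured; Ahsp and Snhg1 had no match by symbol. Some genes stand in more than 1 list. A gene was counted as expressed at 1 TPM or more in each library.

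Spread between libraries was the SD over genes of the log2 ratio of TPM + 0.1 among genes with a mean of at least 1 TPM, divided by the square root of 2. The biological coefficient of variation was the square root of edgeR's common dispersion with an intercept-only design, on estimated counts rounded to whole numbers, with TMM normalization and genes with at least 10 counts in each library. TMM factors were 0.996 and 1.00. Genes counted as more than 2-fold apart had a mean of at least 100 estimated counts, a log2 ratio of TPM + 0.1 over 1 in size and credibility intervals that did not overlap. Gene pairs were called different where both libraries gave the same direction and the intervals of the genes did not overlap in either library.

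For each list, the median log2 ratio of members with a mean of at least 1 TPM was taken from TMM-scaled CPM with 0.5 added to each count, and set among the medians of 10000 random lists of the same size drawn within 20 bins of mean expression. A list was called outside the central range below percentile 2.5 or above percentile 97.5. Random lists hold unrelated genes, so a percentile describes a list and is not a probability. Alternatives covered the expression threshold, posterior means, rescaling to nuclear protein-coding genes, DESeq2 size factors and dispersions, filters on low values, a pseudocount of 1, counts without length correction and each replicate left out. Further alternatives chosen after seeing the data were protein-coding genes only, a robust spread, a protein-coding background for the lists, and shares without spike-ins.

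The calculations were tested on simulated data with the means and library sizes of the real genes. A simulated biological coefficient of variation of 0.05, 0.1 or 0.2 was estimated as 0.05, 0.0991 and 0.199 over 17656, 17643 and 17516 genes. With a simulated coefficient of 0.1 the 2-fold rule, run on counts per library total with intervals from counting error, took 100% of 50 genes raised 3-fold and of 50 lowered 3-fold, 2% and 4% of genes changed 1.5-fold up and down, and 0% of 12830 unchanged genes. With the coefficient found between the libraries, 0.199, it took 92% and 98% of genes changed 3-fold up and down, 16% of genes changed 1.5-fold in each direction and 221 (1.72%) of 12823 unchanged genes. A list of 15 genes raised 1.5-fold reached percentile 100, and a list of 15 unchanged genes percentile 3.89. Work was done in R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.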

Results

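Total RNA of embryonic mouse heart was measured by RNA sequencing in 2 libraries, each made from pooled hearts taken at embryonic day 16.5 from male and female embryos of the B6NCrl strain. The labels number the libraries as biological replicates of a single group, with separate biosamples but 1 donor identifier. They were treated here as separate pools, an assumption on which the biological coefficient of variation and the differences between pools rest. Each pool gave a single library, so differences between the pools cannot be told apart from differences in library preparation. The pool of replicate 2 held hearts of 41 embryos, and the number in the pool of replicate 1 is not stated in the labels. At this stage the chambers are septated, the ventricular wall is compacting and heart muscle cells still divide. Each library started from 10 ng of RNA longer than 200 nt, with ERCC spike-in RNAs added. The gene tables hold 37160624 estimated counts for replicate 1 and 40360242 for replicate 2, of which 36559899 and 38982917 lie on annotated mouse genes. The labels name no second condition, so the comparisons are descriptive. They ask which genes the embryonic heart expressed and at what level, how related genes and transcripts shared that expression, and where the pools differed. Unless stated otherwise, values are the mean ± SD of the 2 libraries (n = 2) in TPM, the length-corrected relative abundance of transcripts, and log2 ratios between the libraries are replicate 2 over replicate 1. For gene lists and their members these ratios were taken from TMM-scaled CPM, and for genes more than 2-fold apart from TPM + 0.1. Genes outside the rule for named genes were chosen after their values were seen, and are said to be so.

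Contractile, blood and energy genes led the profile. Among nuclear protein-coding genes the highest were the adult-type globins Hba-a2 (32045 TPM ± 4013), Hbb-bs (16690.1 ± 2455), Hba-a1 (12763 ± 994) and Hbb-bt (10321 ± 1118), which carry oxygen in red blood cells. Cardiac alpha-actin, Actc1 (ENSMUSG00000068614.7; mm10 chromosome 2, 114047282 to 114053548), stood between Hba-a1 and Hbb-bt at 12435 TPM ± 301. Next came cardiac troponin T, Tnnt2 (8225 ± 304) and the ventricular light chain Myl2 (7259.9 ± 1295). The 20 highest also held the ATP synthase subunits Atp5b (5693 ± 14.6) and Atp5g3 (2686 ± 229.8), the atrial peptide Nppa (4492 ± 1119.6), the thin-filament genes Tpm1 (4230.0 ± 15.3), Tnnc1 (4059.6 ± 1.39), Tnni1 (3709 ± 454) and Tnni3 (3236 ± 9.18). The myosin genes Myl3 (4109 ± 698), Myl7 (3501 ± 851) and Myh7 (2909 ± 472) were also among them. So were the prolyl isomerase Ppia (3233 ± 9.28) and the glycolytic genes Gapdh (3229 ± 436) and Ldha (2690.0 ± 192). Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so the split within each of these pairs is uncertain.

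In all, 14174 genes reached 1 TPM in both libraries, of which 12689 were protein-coding, 465 were processed pseudogenes, 241 were antisense genes and 194 were lincRNA genes. Nuclear protein-coding genes held 80.0% ± 2.85 of the TPM, mitochondrially encoded protein-coding genes 4.72% ± 0.223 and mitochondrial ribosomal RNA 0.586% ± 0.027. The 35 genes of the sarcomere list held 6.38% ± 0.203 and the 4 adult-type globins 7.18% ± 0.858. The 10 highest genes held 13.5% ± 1.03 and the 100 highest 34.7% ± 1.61. Pseudogenes held 5.80% ± 0.608 of the TPM. By share of counts, where short genes weigh less, mitochondrially encoded protein-coding genes held 2.51%, adult-type globins 2.57%, the 10 highest genes 7.62% and pseudogenes 2.05%. The highest of them, singled out after their values were seen, were nuclear copies of mitochondrial genes on chromosome 1, Gm28437 (13015 TPM ± 779.6), Gm29216 (5906 ± 1139) and Gm28661 (5423 ± 275). They share sequence with the mitochondrial genome, so reads on them and on the mitochondrial genes cannot be assigned with certainty. Short RNA genes such as Rn7s1 and Rn7s2 (7487 ± 1948 and 7487 ± 1949), also chosen after their values were seen, hold large TPM values because TPM divides by a short length, and those copies also share reads.

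The libraries ranked genes alike. Across the 14930 genes with a mean of at least 1 TPM, Pearson's r of log2 TPM was 0.95 and Spearman's rho 0.97; across the 12987 protein-coding genes among them the values were 0.98 and 0.99. These are correlations across genes, which are not independent replicates. The SD of the log2 ratio divided by the square root of 2, an estimate of the spread of a single library, was 0.51 over all such genes, 0.28 over protein-coding genes and 0.16 as a robust estimate from the median absolute deviation. Of the protein-coding genes, 92.6% lay within 1.5-fold of each other in the libraries. The biological coefficient of variation estimated by edgeR over 17185 genes with at least 10 counts in each library was 0.199.

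**Figure D1:**
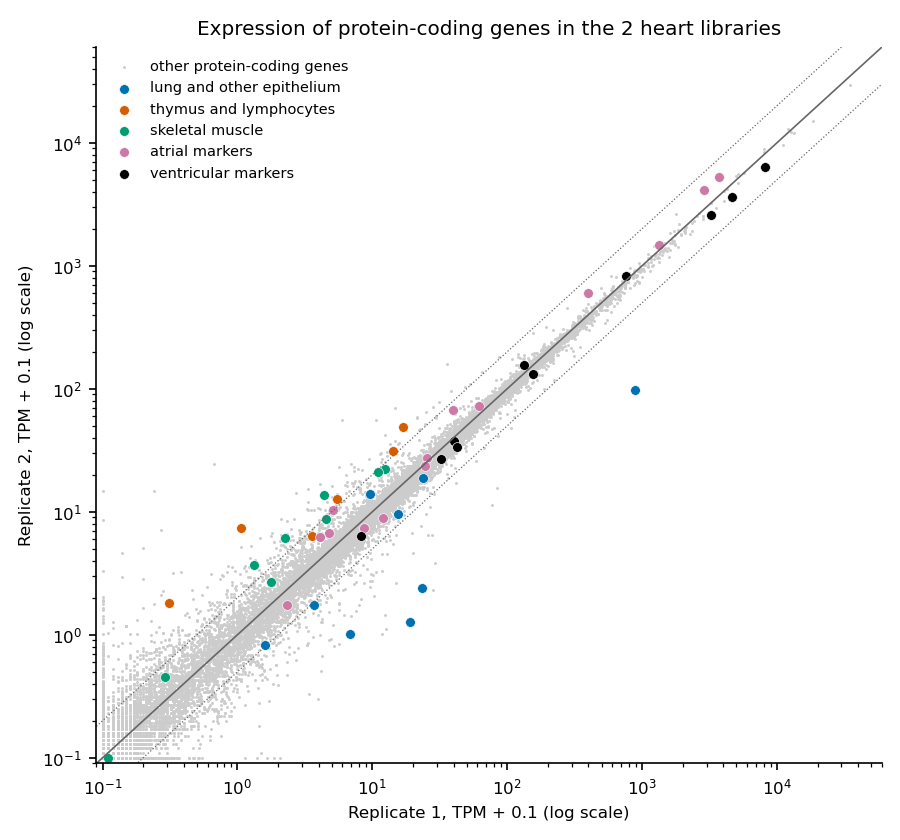
TPM + 0.1 of protein-coding genes in replicate 1 (horizontal, log scale) against replicate 2 (vertical, log scale), 1 grey point per gene, with the members of 5 fixed marker lists in colour; the solid line marks equal values and the dotted lines 2-fold differences. Most genes follow the line, whereas lung markers such as Sftpc (883 and 96.7 TPM) lie below it and thymus markers such as Cd3e (16.9 and 48.7 TPM) above it.

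Every one of the 35 measured sarcomere genes was expressed at 1 TPM or more in both libraries, with a median of 404 TPM. Actc1 exceeded skeletal alpha-actin, Acta1 (180.1 TPM ± 23.3), by 69.3-fold (log2 ratio 6.12 ± 0.22, SD, n = 2), and smooth muscle alpha-actin, Acta2 (1095 ± 137), by 11.4-fold (3.51 ± 0.14). Tnnt2 exceeded slow skeletal troponin T, Tnnt1 (146 ± 6.38), by 56.2-fold (5.81 ± 0.01). Beta-myosin heavy chain, Myh7 (2909 ± 472), the main ventricular form before birth, exceeded alpha-myosin heavy chain, Myh6 (888 ± 99.8), by 3.26-fold (log2 ratio 1.71 ± 0.40). The genes lie next to each other on the minus strand of chromosome 14 in mm10, Myh6 from 54941921 to 54966927 and Myh7 from 54970684 to 54994626. Myl2 exceeded the atrial light chain Myl7 by 2.09-fold, with 2.82-fold in replicate 1 and 1.55-fold in replicate 2. Myl7 exceeded the other atrial light chain, Myl4 (1406 ± 93.2), by 2.46-fold (1.30 ± 0.26, and 0.67 without length correction).

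The slow skeletal troponin I gene, Tnni1, which the heart expresses before birth, and the adult cardiac form, Tnni3, stood close together, at a log2 ratio of 0.32 in replicate 1 and 0.06 in replicate 2. The mean of 0.19 ± 0.18 was about the size of its SD, so these levels were not distinguishable at this replication, although the authors' credibility intervals did not overlap in either library. Other sarcomere genes at high levels, all but titin chosen after their values were seen, were Csrp3 (1570.1 TPM ± 49.9), a Z-disc protein, and Actn2 (1185 ± 58.5), the Z-disc actin crosslinker. Mybpc3 (909 ± 136), cardiac myosin-binding protein C, was also high, as was titin, Ttn (613 ± 62.2). By the rule set for the 25 gene pairs, same direction in both libraries and separate credibility intervals in each, every pair differed, the first gene being higher in 20 and the second in 5. For Tnni1 over Tnni3, Cox6a2 over Cox6a1, Myl2 over Myl7 and Pln over Sln the mean log2 ratio was less than 2 SD from 0. The intervals cover counting and read-assignment error only. With 2 libraries an exact two-sided sign-flip test cannot go below p = 0.5, so no test of a ratio was made.

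**Figure D2:**
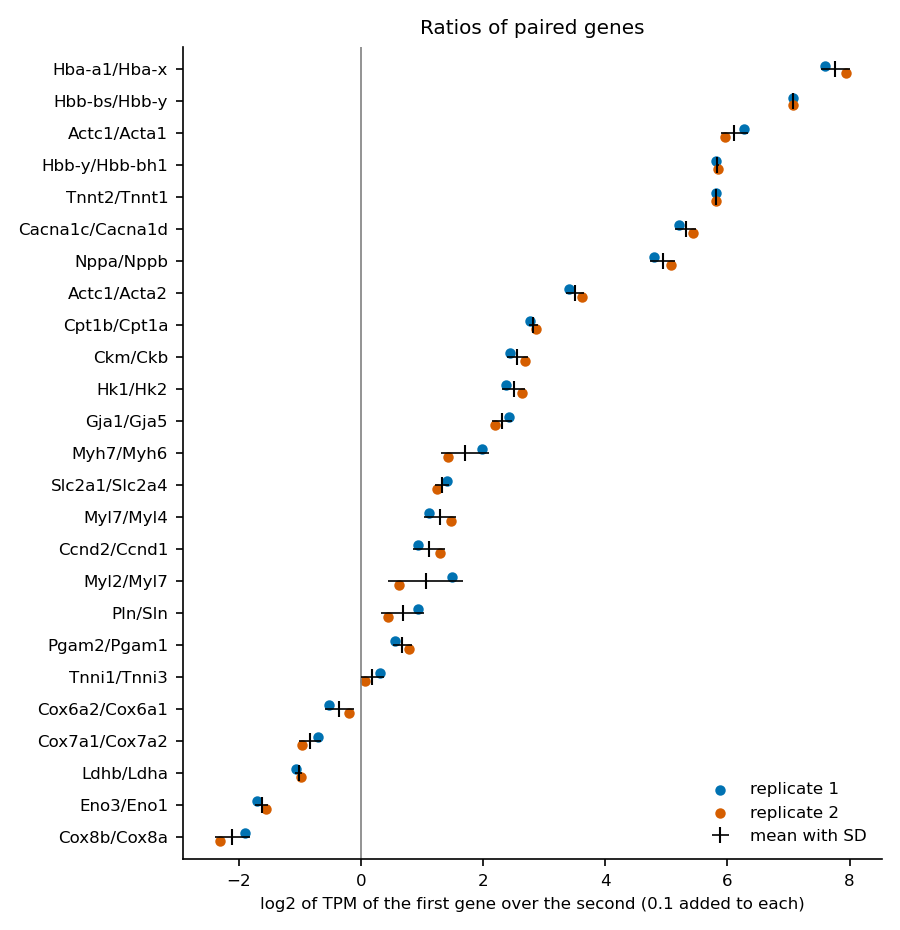
log2 of the TPM of the first gene over the second (horizontal, 0.1 TPM added to each) for 25 gene pairs (vertical), with a blue point for replicate 1, an orange point for replicate 2 and a bar for the mean with its SD (n = 2). Adult over embryonic globins and Actc1 over Acta1 lie at the high end, Cox8b over Cox8a at the low end, and the points of Myl2 over Myl7 stand apart, at 2.82-fold and 1.55-fold.

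All 17 calcium-handling genes reached 1 TPM in both libraries, with a median of 56.4 TPM. The SERCA inhibitor phospholamban, Pln (789.5 TPM ± 42.8), and the luminal calcium buffer Casq2 (545 ± 20.2) were highest. They were followed by the atrial SERCA inhibitor sarcolipin, Sln (501 ± 148), the pump itself, Atp2a2 (243 ± 13.7), and Asph (105 ± 1.24). Pln exceeded Sln by 1.61-fold (log2 ratio 0.69 ± 0.35, and 3.13 with counts not corrected for length). Of the channel and gap junction list, 19 of the 23 measured members reached 1 TPM in both, with a median of 6.12 TPM. Connexin 43, Gja1 (374 ± 19.6), exceeded connexin 40, Gja5 (75.3 ± 4.82), by 4.96-fold (2.31 ± 0.17). The potassium channel genes Kcne1 (144 ± 17.2) and Kcnq1 (28.3 ± 0.841) and connexin 45, Gjc1 (37.4 ± 1.82), came next. The L-type channel gene Cacna1c (56.4 ± 5.395) exceeded Cacna1d (1.32 ± 0.304) by 40.01-fold (5.32 ± 0.17, and 3.64 without length correction). Of the Cacna1c signal, 80.9% ± 1.41 lay on a transcript of 954 nt annotated as processed transcript. The pacemaker channel gene Hcn2 was near the floor, at 1 count in replicate 1 and 2 in replicate 2.

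All 32 cardiac transcription factor genes reached 1 TPM in both libraries (median 16.7 TPM). Highest were the muscle methyltransferase gene Smyd1 (104 TPM ± 6.92) and the homeobox gene Nkx2-5 (104 ± 1.11). Next came Mef2a (90.8 ± 2.84), Gata4 (74.8 ± 11.5) and Tbx20 (61.3 ± 2.45). In the conduction system list, 12 of the 15 measured members reached 1 TPM in both (median 3.53 TPM). It was led by genes that other heart cells also express, Id2 (123 ± 4.504), Gja5, Gjc1, Smoc2 (28.03 ± 2.76) and Tbx3 (6.36 ± 2.04). Cntn2, a marker of the Purkinje network, was near the floor at 0.07 and 0.08 TPM.

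The 14 atrial markers all reached 1 TPM in both libraries (median 25.1 TPM), led by Nppa (4492 TPM ± 1119.6; ENSMUSG00000041616.9, mm10 chromosome 4, 148000722 to 148002079), Myl7 (3501 ± 851), Myl4 (1406 ± 93.2), Sln (501 ± 148) and Dkk3 (67.02 ± 7.53). The 10 ventricular markers did so too (median 144 TPM), led by Myl2, Myl3, Myh7, Pln and the peptide gene Nppb (145 ± 16.6), which lay 30.6-fold under Nppa (log2 ratio 4.94 ± 0.20). Between the libraries the atrial and ventricular lists went opposite ways. The atrial list had a median log2 ratio of 0.41, above all 10000 random lists of the same size and expression. Of its members, 10 of 14 were higher in replicate 2, among them Nppa (0.56), Myl7 (0.55) and Sln (0.66). The ventricular list had a median of -0.27, below all of them. Of its members, 8 of 10 were higher in replicate 1, among them Myl2 (-0.31), Myl3 (-0.32) and Myh7 (-0.29). Pln (0.16) and Nppb (0.28) were the exceptions. Lung, thymus and skeletal muscle markers also differed between these pools, with list medians of -1.08, 1.27 and 1.07.

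Energy metabolism genes were expressed broadly. All 26 nuclear genes of oxidative phosphorylation and energy transfer reached 1 TPM in both libraries (median 930.4 TPM), led by Atp5b, the ADP/ATP carrier Slc25a4 (2368 TPM ± 98.4), Atp5a1 (2103 ± 37.3), Cox4i1 (1975 ± 78.8) and the muscle creatine kinase gene Ckm (1893 ± 62.7). Ckm exceeded the brain form, Ckb (321 ± 26.99), by 5.9-fold (2.56 ± 0.17). Of the cytochrome oxidase subunits with a muscle form and a widely expressed form, the muscle form was lower. The log2 ratios were -2.10 ± 0.29 for Cox8b (399 ± 40.9) over Cox8a (1716 ± 168) and -0.84 ± 0.18 for Cox7a1 (482 ± 64.8) over Cox7a2 (858 ± 6.21). For Cox6a2 (938 ± 13.00) over Cox6a1 (1206 ± 179.7) it was -0.35 ± 0.24. Without length correction these ratios were -2.87, -2.14 and -0.11. The 13 mitochondrially encoded genes had a median of 2200.1 TPM (3768 by posterior means), led by mt-Atp6 (12539 ± 622), mt-Atp8 (8487 ± 619.9), mt-Co1 (5348 ± 254), mt-Cytb (5154 ± 255) and mt-Nd1 (4933 ± 263). Nuclear copies of mitochondrial genes on chromosome 1 also took reads, among them Gm28437 at 13015 TPM, so this order and median are uncertain.

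Glycolytic and fatty acid oxidation genes were both present at high levels. All 19 glycolysis genes reached 1 TPM in both libraries (median 559.7 TPM), led by Gapdh, Ldha, Aldoa (1966 TPM ± 141), Eno1 (1475 ± 190.2) and Pkm (1469 ± 105). Ldha exceeded the heart form of lactate dehydrogenase, Ldhb (1327 ± 40.5), by 2.03-fold (log2 ratio of Ldhb over Ldha -1.02 ± 0.06). Eno1 exceeded the muscle enolase Eno3 (477 ± 25.5) by 3.08-fold (Eno3 over Eno1 -1.62 ± 0.11). Hexokinase 1, Hk1 (193 ± 11.8), exceeded Hk2 (34.3 ± 6.53) by 5.66-fold, with a log2 ratio of 2.37 in replicate 1 and 2.63 in replicate 2. The glucose transporter gene Slc2a1 (118 ± 10.4) exceeded the insulin-responsive Slc2a4 (46.6 ± 0.346) by 2.52-fold (1.33 ± 0.12). The muscle mutase Pgam2 (893 ± 22.99) exceeded Pgam1 (559.7 ± 45.6) at a log2 ratio of 0.68 ± 0.16, a direction that turned to -0.55 with counts not corrected for length. Of the fatty acid oxidation list, 24 of the 25 measured members reached 1 TPM in both (median 168 TPM), led by the fatty acid carrier Fabp3 (1598 ± 95.6), Acadl (729 ± 10.7), Etfb (663 ± 38.8), Acaa2 (623 ± 9.18) and Hadhb (409 ± 25.99). The muscle carnitine palmitoyltransferase gene Cpt1b (197 ± 7.88) exceeded the liver form, Cpt1a (27.8 ± 2.47), by 7.08-fold (2.82 ± 0.07).

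Markers of the other heart cell types were detected throughout. All 21 endothelial genes reached 1 TPM in both libraries (median 44.6 TPM), led by Fabp4 (231 TPM ± 7.93), Ramp2 (167 ± 6.05), Egfl7 (165 ± 22.2), Eng (141 ± 8.12) and Cd34 (95.4 ± 11.4). The 7 endocardial genes (median 14.8 TPM) were led by Cgnl1 (22.4 ± 3.21), Vwf (21.6 ± 0.29), Cytl1 (15.1 ± 1.87), Nfatc1 (14.8 ± 0.028) and Adgrg6 (5.81 ± 0.297). The 6 lymphatic genes (median 12.6 TPM) were led by the chemokine gene Ccl21a (45.1 ± 6.201), which the thymus also expresses, Pdpn (19.4 ± 0.332), Prox1 (13.8 ± 1.17), Lyve1 (11.3 ± 1.02) and Flt4 (5.49 ± 0.962). All 19 fibroblast and interstitial genes were expressed (median 136 TPM). Highest were the matrix genes Sparc (1633 ± 169), Col3a1 (847 ± 149) and Col1a1 (599.7 ± 96.3), vimentin, Vim (703 ± 63.6), and periostin, Postn (357 ± 35.7). The 11 valve genes had a median of 5.75 TPM, led by Postn, Vcan (33.9 ± 6.901), Fmod (21.7 ± 4.15), Sox9 (16.3 ± 0.629) and Col2a1 (7.92 ± 2.02). The 13 epicardial genes (median 16.7 TPM) were led by the keratins Krt8 (151 ± 43.9), Krt18 (142 ± 46.9) and Krt19 (58.97 ± 10.9), with Upk3b (33.9 ± 0.601) and mesothelin, Msln (32.9 ± 0.445). Markers of lung and other epithelium were also detected in these pools, so the keratin levels cannot be assigned to epicardium alone. The 13 smooth muscle and pericyte genes (median 17.8 TPM) were led by Acta2, Mcam (86.6 ± 7.84), Smtn (80.6 ± 8.38), Cnn1 (72.03 ± 4.06) and Tagln (52.8 ± 10.2).

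Adult-type globins stood far above embryonic ones. Hba-a1 exceeded the embryonic alpha-like globin Hba-x (59.2 TPM ± 14.4) by 218-fold (log2 ratio 7.77 ± 0.24). Hbb-bs exceeded the embryonic beta-like globin Hbb-y (124 ± 17.99) by 135-fold (7.07 ± 0.00). Hbb-y in turn exceeded Hbb-bh1 (2.08 ± 0.354) by 56.96-fold (5.83 ± 0.02). The embryonic list had a median of 30.6 TPM. Hbb-bh2, also on the list, had 0 counts in both libraries. That allows up to 3 counts per library, or 0.0802 and 0.0722 TPM for a transcript of 1500 nt. The adult-type list had a median of 14727 TPM. Of the erythroid list, 9 of the 12 measured members reached 1 TPM in both (median 7.22 TPM), led by the heme synthesis gene Alas2 (232 ± 15.3), Bpgm (74.3 ± 1.51), the transferrin receptor Tfrc (41.9 ± 4.09) and Slc25a37 (31.8 ± 3.25). Of the leukocyte list, 18 of the 22 measured members did so (median 8.82 TPM), led by lysozyme, Lyz2 (74.02 ± 3.27), C1qb (34.9 ± 0.643), Tyrobp (27.3 ± 2.34), Pf4 (27.3 ± 0.205) and C1qa (24.5 ± 0.856). The floors cover counting error only.

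Cell cycle genes were expressed throughout. All 24 proliferation genes reached 1 TPM in both libraries (median 84.2 TPM), led by the cyclin gene Ccnd3 (339 TPM ± 17.1), Cdk1 (290.0 ± 15.4), Rrm2 (202 ± 12.5), Birc5 (192 ± 2.46) and Ccnb1 (159.6 ± 4.56). Ccnd2 (87.4 ± 0.24) exceeded Ccnd1 (40.7 ± 7.19) by 2.16-fold (1.11 ± 0.26, and 2.45 without length correction). Of the cell cycle inhibitors, 8 of the 9 measured members reached 1 TPM in both (median 14.9 TPM), led by the imprinted Cdkn1c (154 ± 2.15), Cdkn2d (96.3 ± 7.71), Cdkn1a (64.9 ± 4.35), Meis1 (49.7 ± 2.78) and Cdkn2c (14.9 ± 0.219). Cdkn2a had 0 counts in both libraries. Of the growth factor list, 31 of the 32 measured members reached 1 TPM in both (median 9.8 TPM), led by Igf2 (836 ± 162), Vegfb (120.3 ± 32.05), the endothelin receptor Ednrb (49.8 ± 1.36), Pdgfa (44.6 ± 2.74) and Tgfb2 (34.9 ± 1.95).

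The 21 imprinted genes had a median of 70.1 TPM, with Mest (1498 TPM ± 61.96), Igf2, the noncoding H19 (538 ± 7.95), Grb10 (426 ± 45.2) and the noncoding Meg3 (231 ± 2.85) highest. Of the long noncoding RNAs, 7 of the 9 measured members reached 1 TPM in both (median 9.98 TPM), led by Malat1 (5619 ± 123), Gas5 (243 ± 3.56), Tug1 (68.2 ± 5.06), Xist (15.3 ± 4.38) and Neat1 (9.98 ± 0.17). All 13 splicing regulator genes did so (median 54.99 TPM), led by Srsf1 (138 ± 10.3), Srsf10 (112 ± 6.94), Ptbp1 (110.2 ± 7.09), Celf1 (84.8 ± 7.42) and Mbnl1 (72.2 ± 1.35). Of the immediate early and heat shock list, 11 of the 13 measured members reached 1 TPM in both (median 10.3 TPM), led by Jun (62.6 ± 7.67), Dnajb1 (52.6 ± 0.707), Ier2 (35.2 ± 1.01), Hmox1 (13.8 TPM in each library) and Atf3 (12.9 ± 1.77). The 8 reference genes had a median of 794 TPM, led by Ppia, Eef1a1 (2649 ± 17.2), Actb (2038 ± 326) and Rplp0 (824 ± 41.03).

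Markers of tissues other than heart were detected. The neural and Schwann cell list had a median of 0.62 TPM (0.95 by posterior means), with 6 of the 15 measured members at 1 TPM in both. Its higher members included Stmn2 (4.91 TPM ± 0.75), Tubb3 (4.67 ± 1.19), Erbb3 (3.78 ± 1.004) and Elavl4 (2.69 ± 0.127). The neural crest gene Foxd3 was near the floor at 2 and 4 counts. The liver list had a median of 8.89 TPM (5.39 in replicate 1 and 8.88 in replicate 2), led by transferrin, Trf (48.6 ± 8.36), Apoa1 (10.4 ± 7.86), Ahsg (9.18 ± 1.41), Apoa2 (9.16 ± 0.438) and Afp (8.89 and 8.88 TPM). The cartilage list had a median of 1.76 TPM, led by Col9a1 (5.72 ± 0.445), Cnmd (4.96 ± 0.94), Comp (2.49 ± 0.41), Col11a2 (1.03 ± 0.141) and Matn1 (0.655 ± 0.375). The lung and epithelium list had a median of 11.6 TPM (15.4 in replicate 1 and 2.28 in replicate 2), led by surfactant protein C, Sftpc, at 883 TPM in replicate 1 and 96.7 in replicate 2. Next came Epcam (21.1 ± 3.54), Sftpb (12.7 ± 14.8), Cdh1 (12.4 ± 4.23) and Krt5 (11.6 ± 2.97). The thymus and lymphocyte list had a median of 6.92 TPM (4.42 in replicate 1 and 9.96 in replicate 2), led by Cd3e (32.8 ± 22.5), Ptcra (22.6 ± 11.8), Rag1 (8.98 ± 5.08), Foxn1 (4.86 ± 1.99) and Cd8a (4.15 ± 4.51). The skeletal muscle list had a median of 4.09 TPM (2.14 in replicate 1 and 6.04 in replicate 2), led by Mylpf (17.3 ± 6.99), Tnni2 (15.9 ± 7.16), Tnnt3 (8.94 ± 6.54), Actn3 (6.48 ± 2.94) and Myh8 (4.09 ± 2.76). Pax7, a gene of muscle stem cells, was near the floor at 1 and 0 counts.

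**Figure D3:**
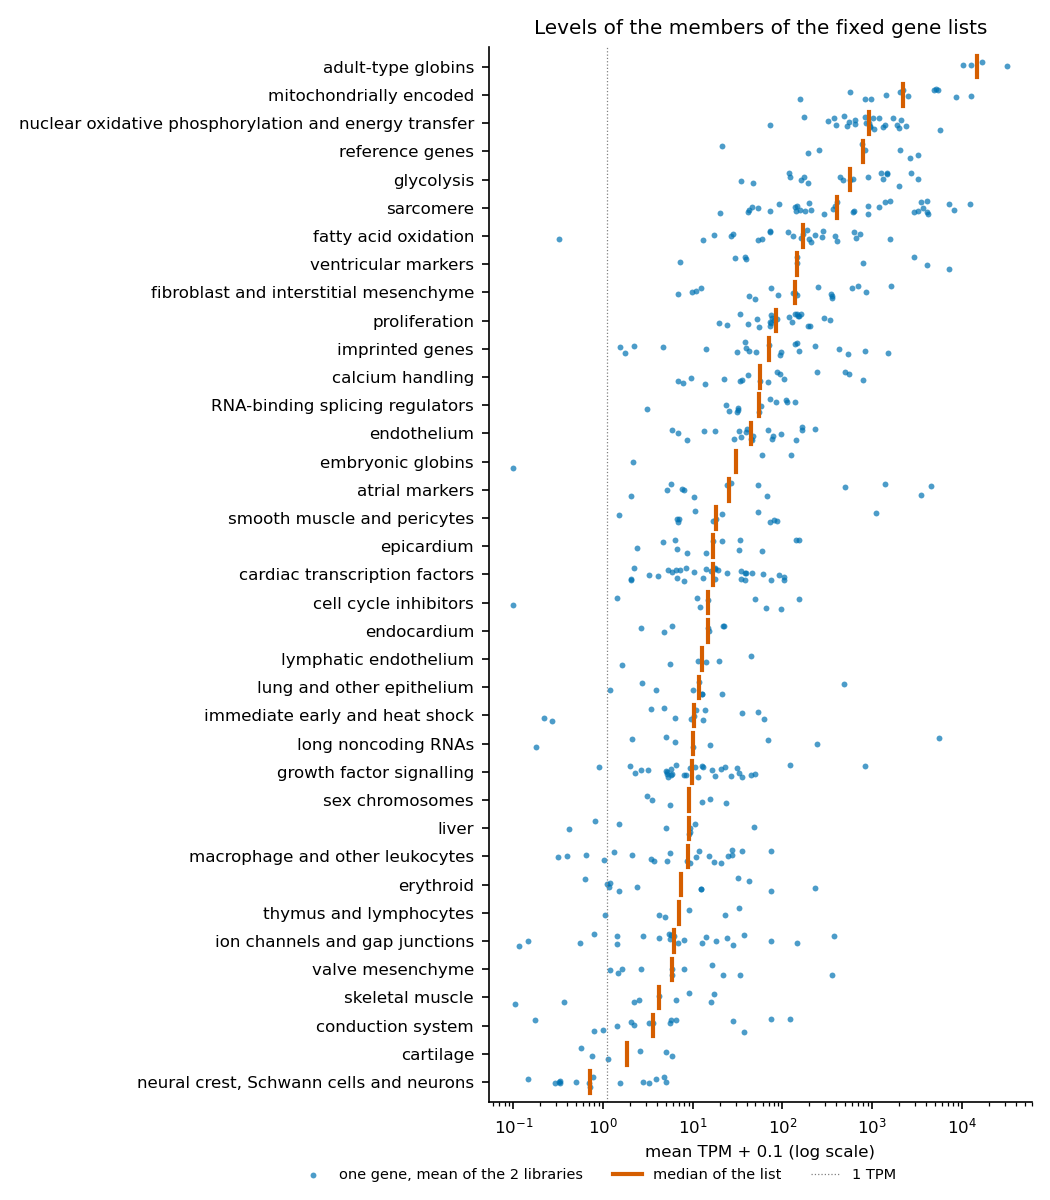
Mean TPM + 0.1 of the 2 libraries (horizontal, log scale) of each member of the 37 fixed gene lists (vertical), 1 blue point per gene, with an orange bar at the list's median and a dotted line at 1 TPM. Medians run from 0.62 TPM for the neural list to 14727 TPM for the adult-type globins.

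At the level of transcripts, 23 of the 30 genes chosen for their alternative splicing or promoter use had a leading transcript with at least 50% of the gene's TPM, and 27 had the same leading transcript in both libraries. The share of the leading transcript had a median SD of 1.96 percentage points and a largest SD of 7.24. A single transcript held nearly all signal in Tpm1 (Tpm1-205, 93.9% ± 0.37), Bin1 (Bin1-202, 99.5% ± 0.25) and Atp2a2 (Atp2a2-202 of 4314 nt, 90.6% ± 0.95, against 9.39% ± 0.93 for Atp2a2-201 of 4491 nt). Cardiac troponin T was split over several, led by Tnnt2-207 (50.2% ± 2.17) and Tnnt2-211 (19.6% ± 0.58). The pyruvate kinase gene Pkm gave 73.6% ± 0.4 to Pkm-202 and 26.4% ± 0.4 to Pkm-201, which are of equal length. Ryr2 gave all estimated counts to Ryr2-201, but posterior means placed 10.96% on Ryr2-202, which has the same length. Nexn and Trdn have a single annotated transcript in the tables, so they entered both counts by construction. Pkm, Ryr2, Bin1 and Fxr1 have 2, so a leading share of at least 50% was fixed in advance for them as well.

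The regulators of muscle genes also had mixed transcripts. The leading shares were 54.8% ± 2.88 for Mef2a, 66.2% ± 1.75 for Mef2c, 53.4% ± 1.34 for Mef2d, 55.1% ± 3.03 for Rbfox2 and 28.96% ± 4.43 for Mbnl1. In Myocd the leading transcript was a processed transcript of 377 nt (47.4% ± 7.13), ahead of a coding form of 5114 nt (40.1% ± 0.42), and in Tead1 it was a retained intron of 646 nt (50.6% ± 6.41). Among Z-disc, calcium and signalling genes the leading share was 57.8% ± 2.62 for Ldb3 and 66.7% ± 4.08 for Pdlim5. It was 42.1% ± 0.7 for Camk2d, 59.6% ± 4.19 for Camk2g and 67.2% ± 6.74 for Kcnip2. For Fxr1 it was 58.8% ± 1.73, and 58.95% ± 1.69 for Numb. In 3 genes the libraries had different leading transcripts, and the higher mean share was 42.3% ± 7.24 for Tpm2, 31.7% ± 3.06 for Fn1 and 30.6% ± 6.82 for Vegfa. Length entered these shares, since TPM counts molecules and a short model needs few reads. In titin, Ttn-215 of 2159 nt held 77.3% ± 0.66 of the gene's TPM and the full-length Ttn-201 of 81843 nt 6.46% ± 0.35.

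A total of 420 genes differed by more than 2-fold between the libraries, 317 higher in replicate 2 and 103 higher in replicate 1, out of 13038 with a mean of at least 100 counts. The 10 largest differences toward replicate 1 included the surfactant protein genes Sftpa1 (log2 ratio -3.90), Sftpb (-3.29), Sftpc (-3.19; ENSMUSG00000022097.3, mm10 chromosome 14, 70520949 to 70524081) and the tight junction genes Cldn18 (-3.61) and Cldn6 (-3.11). Also among them were the alveolar receptor gene Ager (-2.93), the lung and thyroid transcription factor gene Nkx2-1 (-2.76) and the phosphate transporter gene Slc34a2 (-2.67). The others were the pseudogene Gm15725 (7.74 TPM, and listed at 0 in replicate 2) and the alcohol dehydrogenase gene Adh1 (-2.77). Toward replicate 2 the 10 largest included Zg16, a secretory granule gene at 2 and 231 counts (0.14 and 14.5 TPM), and Naaladl1 (3.26) at 15 and 218 counts. They also included the predicted genes Gm10800 (5.19) and Gm10273 (3.22), an Ensembl gene with no match in M21 (3.67) and 5 processed pseudogenes, Gm13443, Gm15920, Gm10093, Gm10012 and Gm7336 (2.97 to 3.95).

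By class, 256 of the 420 were protein-coding, 2.08% of those tested, with 156 higher in replicate 2 and 100 higher in replicate 1. Pseudogenes were 146, 48.7% of the 300 tested, and 144 of them were higher in replicate 2. Among these were copies of ribosomal protein genes such as Rpl3-ps1 (28.2 and 106 TPM) and Rps16-ps2 (52.9 and 131 TPM), named here after their values were seen. Processed pseudogenes resemble the transcripts of their parent genes, so their levels are uncertain. Among protein-coding genes, chosen likewise after their values were seen, replicate 2 was higher for the T-cell genes Cd8a (2.81), Cd8b1 (2.40) and Cd28 (1.96) and the fast skeletal muscle genes Atp2a1 (2.07) and Tnnc2 (2.02). Replicate 1 was higher for Tbx4 (-2.67) and Foxf1 (-2.27), transcription factor genes of lung mesenchyme, and the parathyroid hormone gene Pth (-2.10). The rule compares these libraries only. In a simulation with the means of these genes and the coefficient of variation found between the libraries, 0.199, the rule with intervals from counting error took 46 of 50 genes raised 3-fold and 49 of 50 lowered 3-fold, but also 221 of 12823 unchanged genes (1.72%). That coefficient came from genes with at least 10 counts in each library. Over genes with at least 100 counts in each it was 0.143, a value at which no simulation was run. At a coefficient of 0.1 the rule took 0% of 12830 unchanged genes, so 1.72% may be too high for the genes tested. As the coefficient was estimated from the same libraries, the rule does not separate the 420 genes from their general spread.

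Of the 37 gene lists, 16 had a median log2 ratio outside the central 95% of random lists matched on expression. For independent lists of unrelated genes 1.85 would be expected by chance. Members of a list can share a tissue or regulation and move together, unlike the genes of random lists. The excess over 1.85 is therefore a description and does not measure chance. The lung and epithelium list was lowest (-1.08, 8 of 9 members higher in replicate 1, percentile 0), and lay at -1.97 with members of at least 10 counts in each library. Of the lists outside that range, the thymus (1.27, 5 of 5 members higher in replicate 2, percentile 99.98) and skeletal muscle lists (1.07, 7 of 7, percentile 99.99) were highest, followed by the atrial list given above and the mitochondrially encoded genes (0.15, percentile 99.9). Lower in replicate 2, beside the ventricular list, were the sex chromosome list (-0.38, percentile 0.1), embryonic globins (-0.30, 1.49), and valve genes (-0.24, 0.52). So were adult-type globins (-0.19, 1.08), smooth muscle and pericytes (-0.14, 0.9) and glycolysis (-0.12, 0.08). Smaller differences in that direction were those of endothelium (-0.11, 0.18), growth factor signalling (-0.09, 2.26), cardiac transcription factors (-0.08, 2.06) and fibroblasts (-0.08, 1.92). With members of at least 10 counts in each library, 14 lists lay outside the central range, and the growth factor and transcription factor lists lay inside it, at percentiles 3.86 and 2.97. They also did so against a background of protein-coding genes, chosen after the data were seen, at 4.2 and 4.28. The leukocyte and neural lists then lay outside it, at 98.2 and 99.35. Within the sex chromosome list (median 9.0 TPM), Xist (0.64) and its antisense Tsix (0.80), chosen after its values were seen, were higher in replicate 2. These genes overlap, so their reads cannot be told apart where counting ignores strand. The Y-linked Eif2s3y (-0.37), Ddx3y (-0.40) and Uty (-0.45) were higher in replicate 1.

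The remaining lists lay inside the central range. Among them the sarcomere list was at 0.01 (percentile 67.6), calcium handling at 0.00 (54.1), channels at -0.11 (3.29), conduction at -0.11 (7.09) and epicardium at 0.09 (91.7). Endocardium was at -0.06 (30.98), lymphatic endothelium at -0.12 (10.7), erythroid genes at -0.05 (22.97), leukocytes at 0.10 (96.2), neural genes at 0.50 (95.9), liver at 0.04 (69.8) and cartilage at 0.36 (88.3). Proliferation was at 0.06 (95.3), cell cycle inhibitors at -0.04 (26.9), fatty acid oxidation at 0.00 (53.2), nuclear oxidative phosphorylation at -0.03 (27.96), imprinted genes at -0.01 (31.3) and long noncoding RNAs at 0.04 (74.4). Immediate early and heat shock genes were at 0.07 (86.4), splicing regulators at 0.07 (89.7) and reference genes at 0.04 (82.9).

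**Figure D4:**
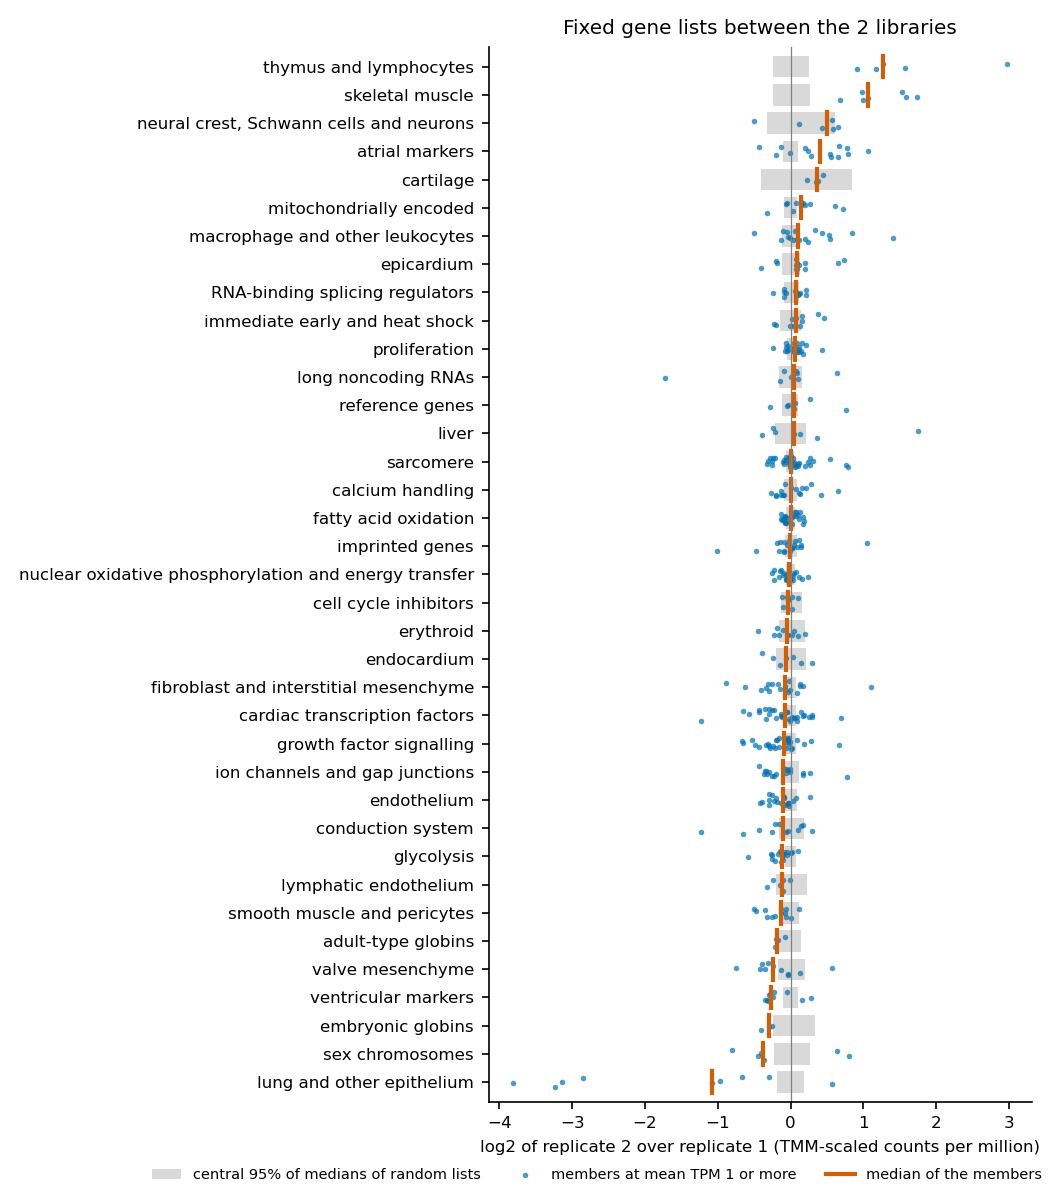
log2 of replicate 2 over replicate 1 in TMM-scaled CPM (horizontal) for the members with a mean of at least 1 TPM of the 37 gene lists (vertical), 1 blue point per gene, with an orange bar at the median and a grey band for the central 95% of medians of 10000 expression-matched random lists. The lung list lies lowest at -1.08 and the thymus list highest at 1.27, with the atrial list at 0.41 and the ventricular list at -0.27.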

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

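The data outside the gene comparisons that carried signal were the ERCC spike-ins and a few of the 26248 rows with a numeric identifier, each above the 3 counts that a count of 0 allows. ERCC spike-ins took 1.616% of the estimated counts in replicate 1 and 3.412% in replicate 2, which is 3.247% and 6.652% of the TPM. Over the 40 spike-ins with at least 100 counts in both libraries, the log2 ratio of counts had a median of 1.18 and an SD of 0.16. Of the rows with a numeric identifier, 1 stood above 3 counts in replicate 1 and 2 did in replicate 2, the highest at 39 and 61 counts.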

How the results depend on the processing

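Alternatives chosen only after the data were seen were protein-coding genes alone, the robust spread, the protein-coding background and shares without spike-ins. No paired analysis was possible because there is a single group. The number of genes more than 2-fold apart was 420. It became 1042 with a mean of at least 10 counts and 54 with at least 1000, settings that test more or fewer genes. For protein-coding genes alone it was 256. They made up 12296 of the 13038 genes tested, but 2.08% of them passed the rule, against 48.67% of the 300 pseudogenes. Over all classes the number lay between 320.0 and 443 under other scalings, posterior means or a pseudocount of 1. Of such genes, 75.5% to 77.9% were higher in replicate 2 whatever the scaling. The spread of 0.506 became 0.253 with a mean of at least 10 TPM, 0.33 with a pseudocount of 1, 0.157 as a robust estimate and 0.282 for protein-coding genes; settings that lower the weight of poorly expressed genes and pseudogenes lowered it. The share of nuclear protein-coding genes, 79.97% of TPM, became 90.43% of counts, where short genes weigh less, and 84.12% without spike-ins. The biological coefficient of variation lay between 0.143 and 0.234.

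Of the gene pairs, Pgam2 over Pgam1 reversed to -0.55 with counts not corrected for length, the setting under which 17 other ratios moved by more than their SD; the cause was not tested. Leaving out each replicate gave 14700 to 15021 detected genes and 511 to 515 list entries at 1 TPM, against 508 entries with both libraries. A gene in more than 1 list counts once per list there, so these are not parts of the 515 measured symbols. Leaving out each replicate also gave 22 to 23 genes with a majority transcript and 77.95% to 81.98% for protein-coding share. All 25 pairs kept the called direction, but the rule for pairs fixed this in advance, as it requires that direction in each library. Of 147 list medians of log2 ratio under alternatives, 138 stayed on their side of the central range, 4 passed it and 5 dropped inside. With TPM the channel and conduction lists passed it, at percentile 1.29 each, and growth factor signalling dropped inside at 3.26. With members of at least 10 counts in each library growth factor signalling (3.86) and cardiac transcription factors (2.97) dropped inside, so that 14 lists rather than 16 lay outside, and the lung list went from -1.08 to -1.97. With TPM the medians of cardiac transcription factors (-0.17), endothelium (-0.17), fibroblasts (-0.18) and smooth muscle (-0.21) were more than 1.5 times as large. The median over all genes with a mean of at least 1 TPM was itself -0.045 with TPM, a shift that TMM scaling removed. Part of these larger medians is therefore an offset shared by all genes. Against protein-coding genes growth factor signalling (4.2) and cardiac transcription factors (4.28) lay inside, with leukocytes (98.2) and neural genes (99.35) outside. Depth limits genes under about 0.1 TPM, where libraries differ by a few counts.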

Other observations

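The tests of a single scaling factor, of length and of direction, the largest ratio among blood genes and the look at intervals of genes with copies were chosen only after their results were seen, as were the gene families described first. Histone genes that are transcribed in S phase contributed 1963 TPM ± 135 in sum (SD, n = 2), with 41 of 64 at 1 TPM or more in both libraries and Hist1h2ap alone at 1219.5 and 1437 TPM. Cytosolic ribosomal protein genes summed to 33029 TPM ± 2005, with 77 of 77 at 1 TPM or more. The PDZ and LIM domain genes, many of which act at the Z-disc, summed to 3484 TPM ± 127, led by Csrp3. Of 39 Hox genes, which pattern the body axis, 3 reached 1 TPM in both libraries.

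Some families differed between the pools. Collagen genes summed to 2904 TPM in replicate 1 and 2284 in replicate 2, with a median log2 ratio of -0.26 below all 10000 random lists and 24 of 32 members higher in replicate 1. Semaphorins and plexins, guidance molecules of vessels and nerves, had a median of -0.28, also below all of them. The lung list moved in the same direction (-1.08), so heart tissue and tissue of other organs are not separated in these values. Constant segments of the T-cell receptor went the opposite way, with a median of 1.34 above all random lists and 6 of 6 members higher in replicate 2, among them Trbc1 and Trbc2, which also stand among the thymus genes tested. Ribosomal protein genes (-0.06, percentile 0.06), integrins (-0.14, 1.57) and the 4 Hox genes with a mean of at least 1 TPM (-0.81, 0.63) lay below the central range, the integrins inside it with TPM (percentile 3.06) or a protein-coding background (2.7). ADAMTS proteases (-0.15, 4.07) and PDZ and LIM domain genes (-0.06, 10.5) lay inside it, but below it with TPM (1.32 and 2.44). Annexins (-0.06, 14.1) and histones (0.01, 57.99, with a median of -0.04 with TPM) lay inside it.

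For the 420 genes more than 2-fold apart, 100 simulated pairs of libraries with Poisson noise alone held at most 0 such genes. The rule's minimum of 100 counts and its separate intervals leave little else possible, so the simulation adds little against counting noise. Reads without molecular identifiers can also vary more than that. Noise without a direction puts as many genes on each side. At least 60.78% of the protein-coding genes past the rule were higher in replicate 2 under 4 scalings (binomial SD 3.28 for independent genes). That argues against noise independent between genes as the whole cause. Genes that share reads or a tissue are not independent, and genes with pseudogene names such as Rpl9-ps6 and Ftl1-ps1 are among them. Noise shared between genes therefore stays open. For a trend with gene length, 403 of the 420 were still apart once the median ratio of genes of like length was subtracted. This argues against a trend common to all genes of like length as the whole cause. Those medians are set mostly by genes that changed little, so a trend in part of the genes stays open. Median length was 1231 nt for genes higher in replicate 2 and 2415 nt for those higher in replicate 1 (2057.5 and 2429.6 nt among protein-coding genes). A different blood content is argued against as the cause of differences of this size by the erythroid list, with a median log2 ratio of -0.05, and by the largest size of 0.45 among erythroid and globin genes, but a small difference stays open, as adult-type (-0.19, 4 of 4 members) and embryonic globins (-0.30, 3 of 3) were lower in replicate 2. Reads shared between pseudogenes and their parent genes could account for the pseudogenes and stay open: the 102 with narrow credibility intervals had a median log2 ratio of 0.762 (bootstrap SD 0.28) with 47 more than 2-fold apart, past the 0.5 set beforehand as arguing against this but by less than that SD, and the 124 with wide intervals 1.07 with 60 apart, a difference of 0.305 (95% interval -0.38 to 0.81) where the explanation needs 0.5; nor do narrow intervals show that reads are a gene's own, as 3 of 9 genes with close copies had them (Hba-a1, Hba-a2 and Gm29216). The design has a single group, so no biological explanation based on groups was tested.

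Markers of neighbouring organs and of the chambers differed between the pools, and the atrial median minus the ventricular median was 0.677, which a single scaling factor forbids. A candidate explanation is tissue of other organs dissected with the hearts, tested on 10 further genes per organ whose values had not been looked at, keeping those with at least 10 counts in either library rather than a mean of 1 TPM. For thymus, 10 of 10 were higher in replicate 2 (median 0.777, percentile 99.95, and 0.72 for the 8 at a mean of 1 TPM), and the most abundant, Trbc2 and Trbc1, were at 70.4 and 37.6 TPM in replicate 1 and 189.9 and 117.8 TPM in replicate 2. For skeletal muscle the median was 0.677 with 6 of 8 higher in replicate 2, past the 0.5 set beforehand, but inside the central range (percentile 93.9), and only Jsrp1 (5.57 and 4.43 TPM, the opposite direction) and Chrng (0.92 and 1.29 TPM) had a mean of at least 1 TPM, with a median of 0.05, so this stays open. For lung, 7 of 9 were lower in replicate 2 with a median of -0.611, short of the -1 set beforehand but at percentile 0.01. For the 6 at a mean of 1 TPM the median was -0.58. Shh (-2.47), Foxa2 (-2.06, 2.23 and 0.50 TPM) and Foxa1 (-2.04) went far in that direction. Etv5 (23.9 and 15.7 TPM) and Lpcat1 (19.97 and 13.7 TPM), the most abundant and also expressed in other tissues, went less far. So did Cyp2f2 (15.1 and 10.2 TPM) and Abca3 (7.65 and 5.11 TPM). Aqp5 and Rtkn2 were slightly higher in replicate 2. By the bound set beforehand, a higher share of lung tissue in replicate 1 stays open. A difference in how much atrium each pool held stays open too.

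A different mix of male and female embryos may underlie the sex-linked transcripts. The log2 ratio of Xist, expressed from the inactive X chromosome of females, minus the median of 4 Y-linked genes was 1.067, with Xist at 0.64 and the Y-linked genes between -0.80 and -0.37. The labels state pooled male and female embryos without their numbers, so the mix itself was not tested.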
